A study of Mus musculus with 16 samples.

How the data were processed

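Ear skin of mice was profiled on 16 arrays, 4 in each of 4 groups given by the labels. Wild-type C57BL/6J mice and miR-146a knockout mice, aged 8 to 11 weeks, received on the right ear either a vehicle control or a daily 31.25 mg dose of Aldara cream, which holds 5% imiquimod (IMQ), a Toll-like receptor 7 agonist that induces psoriasis-like inflammation in mice. Cream was applied on 3 days and ears were taken on day 4. The composition of the vehicle and the hour of collection are not given in the sources used here. Array numbers 1 to 4 come from the sample titles. The labels do not say whether the samples of a group are separate mice, so p-values measure the spread between these samples.

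The authors deposited log2 values for 41345 transcript clusters of the Affymetrix Mouse Gene ST 2.1 array, made with Affymetrix Expression Console per the submitters' processing notes. The summarisation method, its version and the genome build are not given in the sources used here. The deposited log2 values run from 1.25 to 13.29 and hold 2 decimals, and the array medians lie between 3.21 and 3.28, so no further normalization was applied. Gene symbols were taken from the table of symbols that the authors deposited. It gives 1 symbol to 32471 clusters and none to 8874. Of the symbols tested, 25466 occur in the RefSeq gene table of assembly GRCm38.p6 and 1356 occur there as a synonym. That table served for names and for the order of neighbouring genes, and no coordinates are printed because the build of the array annotation is not named. Older symbols are kept, with the current name beside them at first use. Arrays have no sequencing depth, and their number limits the precision.

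For the 909 genes with more than 1 cluster the cluster with the highest mean over all arrays was used, which left 30943 genes. No filter on dim genes was applied. A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 6.18 prior degrees of freedom). There were 5 contrasts: IMQ minus vehicle in each genotype, knockout minus wild type in each treatment, and the difference between the IMQ effects. Within each contrast p-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p under 0.05 were called. If no gene changed, a share of about 0.05 of the 30943 genes would still have an unadjusted p under 0.05. Every adjusted p given for a gene comes from limma, and an error after ± is a standard error for a log2 change and an SD for a group mean. Comparisons of single values between 4 and 4 arrays used two-sided exact permutation tests, whose smallest p is 0.0286.

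A total of 26 gene lists for cytokine axes, skin compartments and cell types were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Some lists share members, so they are not independent. The neutrophil list shares Hdc with the mast cell list, and S100a8 and other members with the antimicrobial and late cornified envelope lists. The same lists were tested with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. In the order wild type, knockout, vehicle, IMQ and difference of effects, the preset correlation called 15, 17, 15, 8 and 15 lists, the estimated one 9, 9, 2, 0 and 3, and fry 13, 17, 8, 1 and 7. Counts "adjusted over the list alone" adjust p within the list. The groups, contrasts, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names, in each contrast, the 10 largest rises and the 10 largest falls among called genes whose 4 arrays of one group all lie above the 4 of the other (adjusted p alone for the difference of effects), up to 4 members of each list by size of change, and always the miR-146a gene, Irak1 and Traf6. Genes with predicted or family names were not ranked, and 1 list member that the rule would name is not reported here. Genes of the circadian clock were chosen after their values were seen.

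The fit was tested on simulated data with 200 changed genes per contrast on 30943 genes. For the IMQ effect in wild type it recovered 19.4% of changes of 0.5 on the log2 scale, 82.1% of changes of 1 and 100% of changes of 2. For the IMQ effect in the knockout the shares were 13.4%, 80.6% and 100%. For the genotype difference they were 22.4%, 94.0% and 100% with vehicle and 14.9%, 89.6% and 98.5% with IMQ. For the difference of effects they were 1.49%, 55.2% and 97.0%. Unchanged genes called numbered 4 to 7 per contrast. The shares hold for 200 changed genes and independent errors. They are not the recovery in the data, where 4634 genes were called for IMQ in knockout ears.

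Alternatives were a filter keeping genes above the array median on at least 4 arrays, quantile normalization, median centring, eBayes with trend and robust options, array weights, only the compared groups, the array number as a block, every transcript cluster on its own, the means of the muscle and adipocyte lists as covariates, a minimum fold of 2, and leaving out each of the 16 arrays. A block on number within the vehicle arrays alone, and a fit without knockout vehicle arrays 3 and 4, were chosen after seeing the data. The number block was within each genotype for the IMQ effects and their difference, and over all arrays for the genotype differences. Whether equal numbers pair the arrays was checked by correlating deviations from the group means. Wild-type and knockout vehicle arrays of the same number correlated at 0.144 to 0.243 and each of the 4 pairs lay above 0.1, against -0.185 to 0.0925 for other numbers, so the numbers were taken to pair the vehicle arrays. What a number marks is not given, so the pairing is an assumption that rests on these correlations. A planned test of miR-146a seed sites in the changed genes was not run, because it needs a genome sequence not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.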

Results

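Gene expression was measured in 4 wild-type vehicle, 4 wild-type IMQ, 4 knockout vehicle and 4 knockout IMQ ears. The design asks how the loss of miR-146a, a microRNA that restrains NF-kB signalling, alters the skin response to IMQ. Arrays of one group correlated with a mean r of 0.972 for wild-type vehicle, 0.974 for wild-type IMQ, 0.964 for knockout vehicle and 0.970 for knockout IMQ, across transcript clusters. These correlations were lowest in the knockout vehicle group.

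The miR-146a gene itself (symbol Mir146) read 1.87 ± 0.22 in wild-type vehicle and 1.80 ± 0.02 in knockout vehicle ears (SD, n = 4, exact permutation p = 0.629, 0.838 after adjustment over 8 such tests). With IMQ it read 1.97 ± 0.13 and 1.85 ± 0.09 (SD, n = 4, exact permutation p = 0.171, 0.457 after adjustment). Its level lies at the 1.98th percentile of genes, near the floor of the array, so this probe set does not check the genotype labels. Irak1 and Traf6, reported targets of miR-146a that act below Toll-like and IL-1 receptors, differed between genotypes by -0.02 ± 0.14 and -0.17 ± 0.10 in vehicle ears (adjusted p = 0.985 and 0.549). In IMQ ears they differed by 0.01 ± 0.14 and 0.12 ± 0.10 (adjusted p = 0.996 and 0.825). The list of 28 reported targets did not pass between genotypes with vehicle (median -0.05, adjusted p = 0.324), with IMQ (median -0.05, adjusted p = 0.123) or in the difference of effects (median 0.02, adjusted p = 0.767).

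In wild-type ears IMQ raised genes of myeloid recruitment and lowered genes of the differentiated epidermis. The largest rise was that of Cxcl13, a chemokine for B cells, by 5.06 ± 0.30 on the log2 scale (at least 33.4-fold, n = 4 and 4, adjusted p = 3.46e-08). Saa3, an acute-phase protein, rose by 3.79 ± 0.40, Retnlg by 3.18 ± 0.24, the macrophage chitinase-like gene Chil3 by 3.03 ± 0.21, the neutrophil chemokine Cxcl3 by 2.94 ± 0.40 and the siderophore-binding Lcn2 by 2.77 ± 0.28. Ifi205 (2.69), Serpina3n (2.37), Cxcl1 (2.30) and Stfa2l1 (2.18) completed the 10 largest rises. Vehicle means of Cxcl13 (3.28), Chil3 (3.27), Cxcl3 (3.32) and Retnlg (2.54) lay near or below the array medians, where background limits a fold, so their changes are lower bounds and their ranks are uncertain. The largest falls were those of the epithelial metallothionein Mt4 (-2.62 ± 0.23), the epidermal lipoxygenase Alox12e (-2.49 ± 0.16), the keratins Krt77 (-2.33) and Krt24 (-2.25) and the filaggrin relative Flg2 (-2.22 ± 0.22). They were followed by Sema3d (-2.21), Guca2a (-1.82), Cyp2g1 (-1.77), Frem2 (-1.76) and Bbox1 (-1.76). With IMQ Cyp2g1 (3.15) and Frem2 (2.99) ended below the array medians, so their falls are lower bounds too.

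Among monocyte and macrophage markers 12 of 26 rose in wild-type ears (19 adjusted over the list alone, median 0.82, camera adjusted p = 2.77e-24), including Itgam (2.16), Ccl7 (2.18) and Emr1, now Adgre1 (1.63). Of the neutrophil markers 10 of 25 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 6.31e-10), with Mmp8 at 1.84. The mast cell list had 4 of 12 rising (7 adjusted over the list alone, camera adjusted p = 3.02e-09), among them Hdc (1.61, also in the neutrophil list), Tpsb2 (1.17) and Cma1 (0.94). Endothelial genes rose in 9 of 20 cases (14 adjusted over the list alone, camera adjusted p = 2.37e-13), for example Selp (1.74). Antimicrobial proteins rose in 7 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.78e-08), with S100a8 at 1.79 and S100a9 at 1.43. Neutrophil chemoattractants rose in 4 of 11 cases (6 adjusted over the list alone, camera adjusted p = 3.22e-07), with Tnf at 1.01. NF-kB pathway genes rose in 6 of 31 cases (11 adjusted over the list alone, camera adjusted p = 7.34e-08), among them Tnfaip2 (1.21).

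The IL-17 and IL-23 list shifted upwards in wild-type ears (camera adjusted p = 0.00118), where Ccl20, the ligand of Ccr6, rose by 1.73 ± 0.16, Zc3h12a rose by 0.81 ± 0.19 and Il22ra1 fell (-0.77 ± 0.14). In this list 3 of 22 rose and 1 fell (6 and 1 adjusted over the list alone). Il17f read 0.75 ± 0.36 (adjusted p = 0.354) and Il17a 0.04 ± 0.18 (adjusted p = 0.956). The mean level of Il17a was 2.56 to 2.78 in the 4 groups, near the lower quartile of the arrays (2.50 to 2.60), so this reading does not show that Il17a did not change. Late cornified envelope genes fell in 17 of 37 cases and rose in 1 (23 and 4 adjusted over the list alone, median -0.54, camera adjusted p = 2.27e-13), with Lce1c at -1.46 and Lce1m at -1.48. Stress keratins and small proline-rich proteins rose in 10 of 21 cases (14 adjusted over the list alone, median 0.87, camera adjusted p = 2.37e-13, adjusted p = 0.0620 with an estimated correlation), with Il19 at 1.92 and Sprr2d at 1.56. The IL-1 and IL-36 family had 3 of 17 rising and 2 falling (6 and 2 adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.118 with an estimated correlation), where Il1r1 (0.92) and Il1a (0.84) rose and Il18 (-0.94) fell. T and NK cell markers shifted downwards with 2 of 23 falling (2 adjusted over the list alone, camera adjusted p = 0.0176, adjusted p = 0.0726 with an estimated correlation), namely the dendritic epidermal T cell receptor gene Tcrg-V5, now Trgv5 (-0.92), and Cd3g (-0.68). The adipocyte list shifted upwards with 2 of 22 rising, Cidec (1.26) and Fabp4 (1.02) (5 adjusted over the list alone, camera adjusted p = 1.10e-04, adjusted p = 0.341 with an estimated correlation). Cartilage markers fell in 2 of 19 cases (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.00213, adjusted p = 0.0566 with an estimated correlation). Immediate early genes rose in 1 of 18 cases (4 adjusted over the list alone, camera adjusted p = 0.00459, adjusted p = 0.420 with an estimated correlation). Skeletal muscle (median 0.08, camera adjusted p = 0.449) and cell cycle genes (median -0.02, camera adjusted p = 0.959) did not pass, nor did interferon-stimulated genes (camera adjusted p = 0.105), of which Ifi27l2a (1.19) and Iigp1 (0.84) rose. The hair follicle (camera adjusted p = 0.0546), sebaceous (0.879), fibroblast (0.674), Langerhans and dendritic cell (0.152), B cell (0.309), melanocyte (0.714) and erythroid lists (0.372) did not pass either. Median and mean had opposite signs for sebaceous genes (0.10 and -0.06) and for the fibroblast list (-0.09 and 0.01). In all, 1126 genes were called in wild-type ears, 603 higher and 523 lower, of which 269 changed at least 2-fold. The balance depended on the scaling, with 742 higher and 433 lower after median centring and 553 and 560 after quantile normalization. There were 535 calls with muscle and adipocyte means as covariates.

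**Figure D1:**
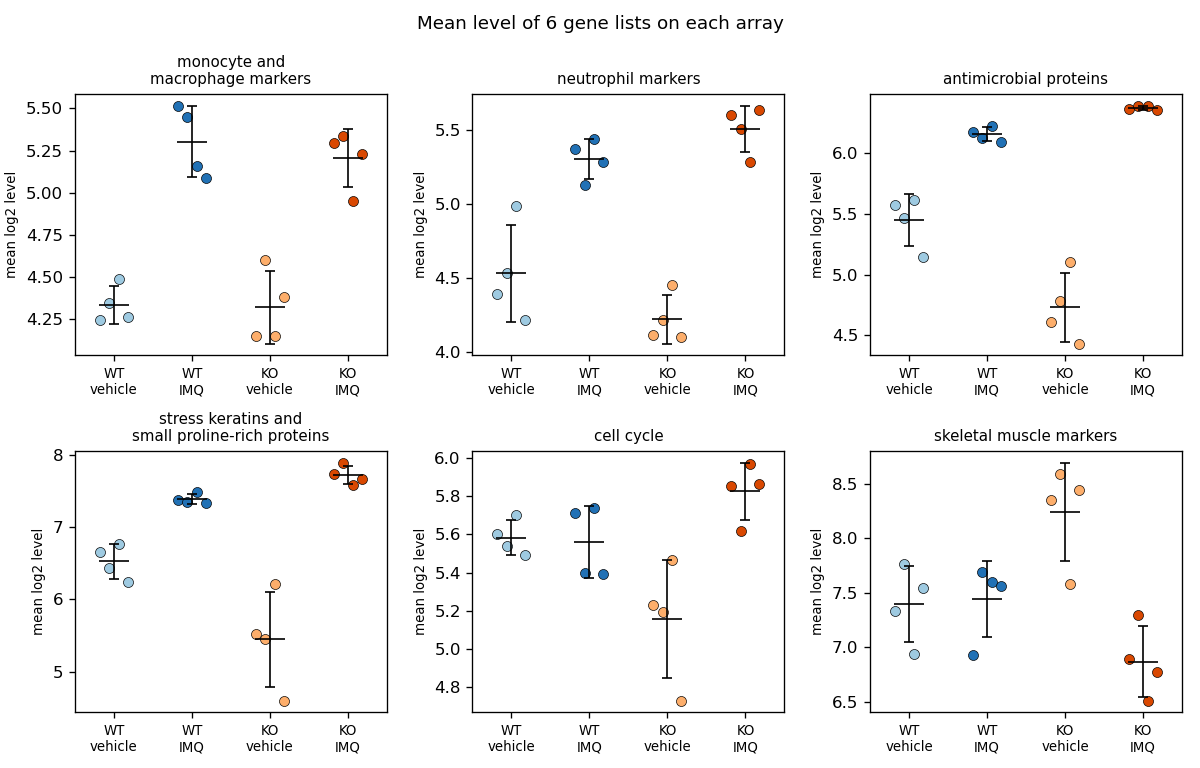
Mean log2 level of the genes in 6 lists on each array, with a point per array, the mean as a horizontal line and the SD as an error bar (n = 4 arrays per group; WT, wild type; KO, knockout). The stress keratin mean was 6.52 in wild-type vehicle and 5.44 in knockout vehicle ears, and the skeletal muscle mean was 8.24 in knockout vehicle and 6.87 in knockout IMQ ears.

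In knockout ears IMQ raised genes of myeloid recruitment, epidermal stress, antimicrobial defence and the cell cycle, and lowered muscle and cartilage genes. The cell cycle and muscle lists were called by camera with the preset correlation and by fry (adjusted p = 6.20e-04 and 4.78e-04), but not by camera with an estimated correlation (0.0798 and 0.0781). Saa3 rose by 4.78 ± 0.40 on the log2 scale (27.5-fold, n = 4 and 4, adjusted p = 3.13e-07), the cytokine Il1b by 4.46 ± 0.73, the chemokine Ccl3 by 4.06 ± 0.63, Cxcl13 by 4.05 ± 0.30 and the beta-defensins Defb4 and Defb3 by 4.04 ± 0.25 and 4.04 ± 0.32. Sprr2e (4.04), Cxcl3 (3.71), Stfa2l1 (3.65) and S100a8 (3.48) rose as well. In knockout vehicle ears Defb3 (3.35) and Cxcl3 (2.73) also started near or below the array medians. Probe sets of the Sprr2, Lce3, Stfa and beta-defensin families can share sequence, so members within a family are not independent. The largest falls were those of Alox12e (-3.93 ± 0.16), Krt24 (-3.89), Flg2 (-3.86), Mt4 (-3.80) and the basal and follicular keratin Krt15 (-3.23 ± 0.14). Falls were also large for Krt77 (-3.15), Lce1m (-2.96), Sema3d (-2.87), the clock-output factor Dbp (-2.57 ± 0.20) and Calm5 (-2.16). Alox12e ended at 3.04 with IMQ, below the array medians, so its fall is a lower bound.

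Stress keratins and small proline-rich proteins rose in 19 of 21 cases in knockout ears (19 adjusted over the list alone, median 2.58, camera adjusted p = 2.63e-26), including Krt6a (3.46), Sprr1a (3.09) and Gjb2 (3.04). Antimicrobial proteins rose in 12 of 18 cases and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 8.56e-14), with Slpi at 3.17. The IL-1 and IL-36 family rose in 8 of 17 cases and fell in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 2.50e-08), with Il1a at 2.28, Il33 at 1.58, Il1f9, now Il36g, at 1.39 and Il1f6, now Il36a, at 1.38. Neutrophil markers rose in 14 of 25 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 3.64e-12). Neutrophil chemoattractants rose in 7 of 11 cases (9 adjusted over the list alone, camera adjusted p = 9.05e-10), with Ptgs2 at 2.76 and Tnf at 1.78. Monocyte and macrophage markers rose in 14 of 26 cases (18 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.78e-11), with Cd14 at 2.73. NF-kB pathway genes rose in 16 of 31 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 9.04e-09), with Bcl3 at 2.17. The IL-17 and IL-23 list rose in 9 of 22 cases and fell in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 5.62e-04), with Il17f at 1.68. Cell cycle genes rose in 33 of 46 cases (40 adjusted over the list alone, median 0.65, camera adjusted p = 1.22e-21, adjusted p = 0.0798 with an estimated correlation), including Mcm3 (1.18), Rrm2 (1.15) and Cdc20 (1.09).

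Skeletal muscle markers fell in 33 of 33 cases in knockout ears (33 adjusted over the list alone, median -1.34, camera adjusted p = 8.08e-27, adjusted p = 0.0781 with an estimated correlation), among them Tcap (-2.13), Casq1 (-2.09) and Pvalb (-2.01), beside the rise of the epidermal lists. Cartilage markers fell in 11 of 19 cases (12 adjusted over the list alone, camera adjusted p = 1.32e-09), with Lect1, now Cnmd, at -1.80, Chad at -1.73 and Comp at -1.38. Adipocyte markers fell in 5 of 22 cases (6 adjusted over the list alone, camera adjusted p = 4.57e-05, adjusted p = 0.315 with an estimated correlation). Antigen-presentation genes H2-Ab1 (-0.99) and Cd74 (-0.98) fell within the Langerhans and dendritic cell list, where 7 of 22 fell (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.00389, adjusted p = 0.0555 with an estimated correlation). Immediate early genes rose in 10 of 18 cases (12 adjusted over the list alone, camera adjusted p = 5.03e-07, adjusted p = 0.175 with an estimated correlation). Endothelial genes rose in 7 of 20 cases (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.339 with an estimated correlation). Interferon-stimulated genes rose in 4 of 38 cases (3 adjusted over the list alone, camera adjusted p = 0.00245, adjusted p = 0.292 with an estimated correlation), with Slfn4 at 2.94. Haemoglobin and erythroid genes fell in 1 of 8 cases (3 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.102 with an estimated correlation). The fibroblast and matrix list did not pass (median -0.11, mean 0.01, camera adjusted p = 0.371), although Tnc (2.46) and Mmp3 (1.86) rose within it. Nor did the T and NK cell (camera adjusted p = 0.396), mast cell (0.327), B cell (0.516), hair follicle (0.741), sebaceous (0.338) and melanocyte lists (0.338). Late cornified envelope genes went both ways, 11 rising and 16 falling of 37 (11 and 17 adjusted over the list alone, camera adjusted p = 0.141), with Lce3d at 3.12 and Lce3a at 2.55. In all, 4634 genes were called in knockout ears, 2496 higher and 2138 lower, of which 821 changed at least 2-fold. These were 2754 and 1846 after median centring and 2260 and 2288 after quantile normalization. With muscle and adipocyte means as covariates 612 genes were called, and without knockout vehicle arrays 3 and 4 the number was 3179.

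Both genotypes called 808 genes for IMQ, 427 higher in both, 373 lower in both and 8 in opposite directions, where independent lists would share 48.6 higher and 36.1 lower. These 808 genes were 71.8% of the wild-type calls. Across all genes, which are not independent replicates, the log2 effects of the genotypes correlated at r = 0.547 (Spearman's rho 0.359). Of the wild-type calls 48.3% had the larger effect in the knockout, and over these genes the slope of the knockout on the wild-type effect was 1.03. Being called in wild type favours genes with a large wild-type effect. The share and the slope therefore do not show effects of equal size. Cxcl13, Chil3, Retnlg and Mmp8 rose in both genotypes, and their differences of effect were -1.02 ± 0.42, 0.09 ± 0.29, 0.17 ± 0.34 and 0.00 ± 0.26 (adjusted p = 0.289, 0.942, 0.907 and 0.997). The vehicle means of Chil3, Retnlg and Mmp8 in both genotypes and of Cxcl13 in wild-type ears lay near or below the array medians, so these differences set lower bounds against each other and do not show equal effects.

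**Figure D2:**
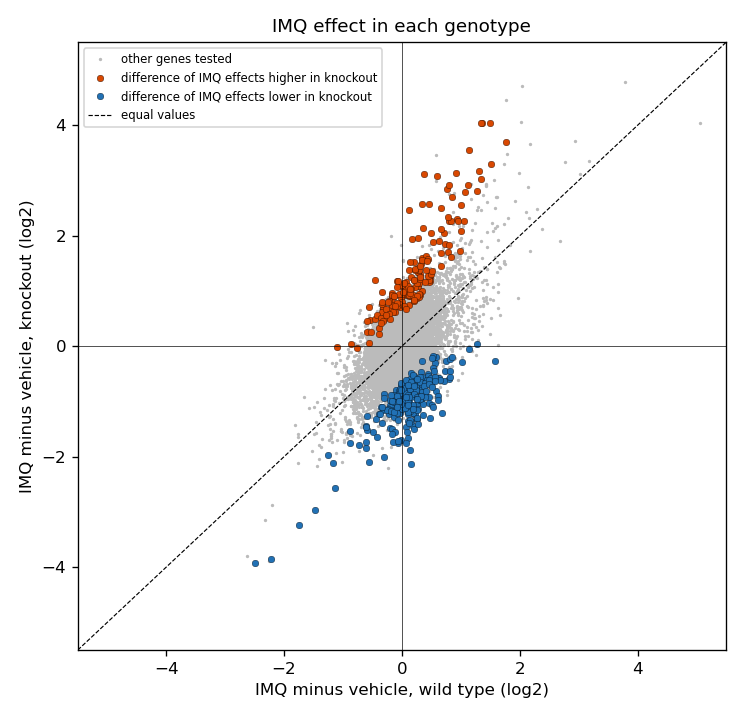
IMQ minus vehicle log2 effect in knockout ears (vertical axis) against that in wild-type ears (horizontal axis), a point per gene, with equal values on the dashed line. Coloured points are the 387 genes called for the difference of effects, 164 higher (orange) and 223 lower (blue) in the knockout.

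Vehicle-treated knockout ears had less mRNA of epidermal stress and defence genes than vehicle-treated wild-type ears. The antimicrobial list kept its call with an estimated correlation (adjusted p = 0.0181) and the stress keratin list did not (adjusted p = 0.0621 with an estimated correlation). Krt6a had the largest negative difference (-2.70 ± 0.55, n = 4 and 4, adjusted p = 0.0326), followed by Lce3d (-2.30 ± 0.36), Sprr1a (-2.14 ± 0.24), Defb3 (-2.13 ± 0.32), Rptn (-1.99) and Defb4 (-1.98 ± 0.25). Cd59a, which encodes an inhibitor of complement lysis, was lower too (-1.96 ± 0.21), as were Sprr1b (-1.86), Gsta4 (-1.74) and Lce3f (-1.72). Lce3f (2.64), Cd59a (3.26) and, as given above, Defb3 lay below or near the array medians in knockout vehicle ears, so these differences are lower bounds. Dbp was higher (1.24 ± 0.20, adjusted p = 0.00963), as were Alad (1.19), an enzyme of haem synthesis, Npr3 (1.02), Atp1b2 (0.92), Nexn (0.94) and the muscle genes Smtnl1 (1.12), Mylpf (1.01), Mustn1 (0.95), Tmod4 (0.95) and Myh3 (0.93). The IL-1 and IL-36 family was lower in 5 of 17 cases (9 adjusted over the list alone, camera adjusted p = 2.89e-09), with Il1a at -1.22, Il33 at -0.88 and Il1f6 at -0.92. Antimicrobial proteins were lower in 3 of 18 cases (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.75e-11), with Slpi at -1.58.

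Stress keratins and small proline-rich proteins were lower in 7 of 21 cases in knockout vehicle ears (15 adjusted over the list alone, median -1.05, camera adjusted p = 1.35e-19, adjusted p = 0.0621 with an estimated correlation). Beside this, skeletal muscle markers were higher, 1 of 33 passing (33 adjusted over the list alone, median 0.82, camera adjusted p = 4.85e-30, adjusted p = 0.111 with an estimated correlation). Cell cycle genes were lower, 1 of 46 passing, namely Aurkb (-0.84; 25 adjusted over the list alone, median -0.44, camera adjusted p = 3.67e-22, adjusted p = 0.112 with an estimated correlation). Late cornified envelope genes were lower in 7 of 37 cases (13 adjusted over the list alone, camera adjusted p = 6.57e-11, adjusted p = 0.111 with an estimated correlation). The other lists called with the preset correlation were lost with an estimated one, though fry still called cartilage (adjusted p = 0.0173) and NF-kB genes (0.0219). Higher in the knockout were the adipocyte (mean 0.50, adjusted p = 0.144 with an estimated correlation), cartilage (0.23, 0.0621) and endothelial lists (0.15, 0.479). Lower were neutrophil chemoattractants (mean -0.51, adjusted p = 0.144 with an estimated correlation), neutrophil markers (-0.31, 0.306), NF-kB (-0.19, 0.111), immediate early (-0.38, 0.216), sebaceous (-0.19, 0.227) and interferon-stimulated genes (-0.11, 0.451). In all, 141 genes were called, 33 higher and 108 lower (55 and 103 after quantile normalization, and 37 and 38 with array number as a block in the vehicle arrays alone). At an unadjusted p under 0.05 there were 3763. With the number as a block Npr3 (adjusted p = 0.0657) and Lyrm7 (0.0681) were no longer called, and with the block in the vehicle arrays alone neither were Krt6a (0.0844), Gsta4 (0.0511), Myh3 (0.0590), Il1f6 (0.0522) and Aurkb (0.0968). The numbers were taken to pair these arrays. With number as a block over all arrays 240 genes were called, 135 of the 141 among them. Equal numbers did not pair the IMQ arrays (r from -0.213 to 0.0741), so that fit is no check of the vehicle pairing. With the block in the 8 vehicle arrays alone the count was 75, of which 44 were among the 141. With only the vehicle groups and no block it was 15, of which 14 were among the 141. With muscle and adipocyte means as covariates it was 2. Leaving out 1 array gave 37 (without wild-type vehicle 1) to 474 genes (without knockout vehicle 3, 200 higher and 274 lower).

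**Figure D3:**
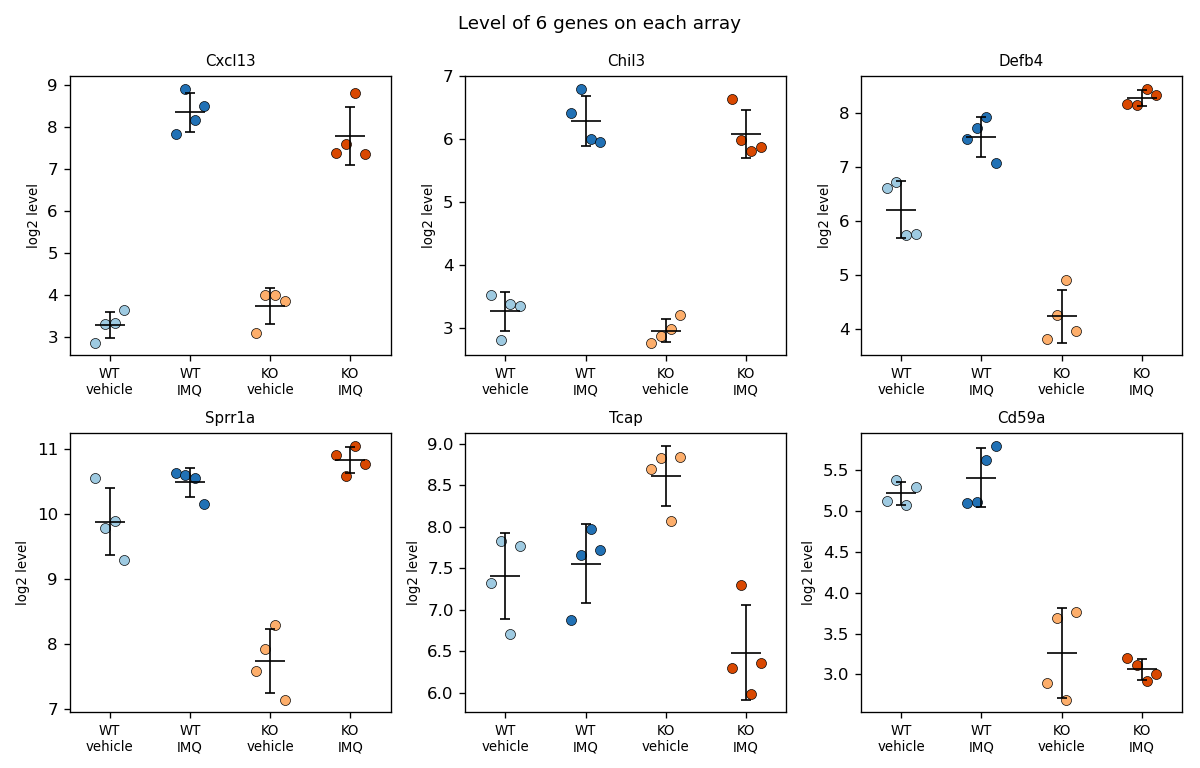
Log2 level of Cxcl13, Chil3, Defb4, Sprr1a, Tcap and Cd59a on each array, with a point per array, the mean as a horizontal line and the SD as an error bar (n = 4 arrays per group; WT, wild type; KO, knockout). Sprr1a read 9.88 ± 0.52 in wild-type vehicle and 7.74 ± 0.49 in knockout vehicle ears, and Cd59a was lower in knockout ears with both treatments.

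Few genes were called between IMQ-treated ears of the 2 genotypes. This does not show that the ears differed little, since 14.9% of simulated changes of 0.5 were recovered in this comparison. For 1554 genes the 4 arrays of one genotype all lay above those of the other, where chance gives about 884. Cd59a was lower in the knockout (-2.35 ± 0.21, n = 4 and 4, adjusted p = 5.24e-05), followed by Myoc (-1.62 ± 0.18), Flg2 (-1.48 ± 0.22), Alox12e (-1.27 ± 0.16), the selenoprotein Gpx3 (-1.06), the proteoglycan Omd (-1.04), Angptl7 (-1.04), Ccl20 (-1.02 ± 0.16), the kinase Wnk4 (-1.01) and Entpd4 (-0.94 ± 0.10). Higher in the knockout were the mitochondrial assembly factor Lyrm7 (1.02 ± 0.12, adjusted p = 0.00121), the epidermal phospholipase Pla2g4d (0.79), Defb14 (0.72), Rnf224 (0.71) and Crabp2 (0.66). Cd59a (3.06) and Alox12e (3.04) in knockout IMQ ears, and Lyrm7 (3.04) and Rnf224 (2.57) in wild-type IMQ ears, lay below the array medians, so their differences are lower bounds. Defb4 read 0.72 ± 0.25 and Sprr1a 0.34 ± 0.24 (adjusted p = 0.402 and 0.765). Skeletal muscle markers shifted downwards with none of 33 passing over all genes (18 adjusted over the list alone, median -0.59, camera adjusted p = 2.03e-19, adjusted p = 0.407 with an estimated correlation). Cell cycle genes shifted upwards with none of 46 passing (median 0.25, camera adjusted p = 9.59e-11, adjusted p = 0.407 with an estimated correlation). Stress keratins (median 0.32, adjusted p = 0.407 with an estimated correlation), antimicrobial proteins (0.14, 0.407), neutrophil markers (0.20, 0.407), mast cell (-0.36, 0.160), adipocyte (-0.31, 0.407) and cartilage markers (-0.31, 0.0885) were also called with the preset correlation and not with an estimated one. Fry called the cartilage list alone (adjusted p = 0.0288). In all, 37 genes were called, 6 higher and 31 lower, with 2551 at an unadjusted p under 0.05. With only these groups 11 genes were called, with the covariates 10, and leaving out 1 array gave 7 (without wild-type IMQ 2) to 80 (without knockout IMQ 3).

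Cd59a, Entpd4, Ccl20, Lyrm7 and 3 genes with predicted names (Gm21464, Gm20236 and Gm10002) differed between genotypes in the same direction in both treatments. Independent lists would share 0.169 genes, and 10 were called in both. With vehicle the differences were -0.88 ± 0.10 for Entpd4, -0.79 ± 0.16 for Ccl20 and 0.57 ± 0.12 for Lyrm7 (adjusted p = 5.17e-04, 0.0354 and 0.0481). Crabp2, Krt15 and Per1 differed in opposite directions in the 2 treatments. With the block in the vehicle arrays alone the vehicle difference was no longer called for Lyrm7 (adjusted p = 0.0933), Crabp2 (0.128) and Krt15 (0.0557).

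The IMQ effect differed between genotypes for genes of the stressed epidermis, whose effect was more positive in the knockout, and for muscle genes, whose effect was more negative. Both lists were called by camera with the preset correlation and by fry (stress keratins adjusted p = 0.00812 and skeletal muscle 0.0122), but not with an estimated correlation (0.0703 and 0.0768), and 0 genes were called by limma with muscle and adipocyte means as covariates (2374 at an unadjusted p under 0.05). Lce3d differed by 2.74 ± 0.51 on the log2 scale (adjusted p = 0.0144), Defb4 by 2.70 ± 0.35, Defb3 by 2.67 ± 0.46, Sprr2e by 2.55 ± 0.55 and Sprr1a by 2.48 ± 0.34. Rptn (2.34), Sprr1b (2.24), Gsta4 (2.12), S100a7a (2.11) and Slpi (1.87) completed the 10 largest. Defb3 lay near the array medians in knockout vehicle ears, so its difference is a lower bound and its rank is uncertain. On the other side stood Tcap (-2.28 ± 0.41, adjusted p = 0.0128), Myh4 (-2.02), Lyz1 (-1.89), the transcription factor Zbtb16 (-1.85), Myoz1 (-1.81), Myoc (-1.78), Myom1 (-1.76), Pvalb (-1.70), Cacna1s (-1.70) and Smtnl1 (-1.70). Stress keratins were higher in 7 of 21 cases (17 adjusted over the list alone, median 1.47, camera adjusted p = 1.41e-18, adjusted p = 0.0703 with an estimated correlation). Antimicrobial proteins were higher in 5 of 18 cases (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.43e-09). The IL-1 and IL-36 family was higher in 5 of 17 cases (8 adjusted over the list alone, camera adjusted p = 7.78e-07). Cell cycle genes were higher in 6 of 46 cases (32 adjusted over the list alone, camera adjusted p = 1.56e-25, adjusted p = 0.107 with an estimated correlation), among them Plk1 (1.16). Skeletal muscle markers were lower in 18 of 33 cases (33 adjusted over the list alone, median -1.45, camera adjusted p = 2.66e-37, adjusted p = 0.0768 with an estimated correlation). Cartilage markers were lower in 3 of 19 cases (9 adjusted over the list alone, camera adjusted p = 7.78e-07), with Acan at -1.14. Adipocyte markers were lower in 2 of 22 cases (12 adjusted over the list alone, camera adjusted p = 1.25e-12, adjusted p = 0.129 with an estimated correlation). Late cornified envelope genes went both ways, 6 higher and 2 lower of 37 (13 and 3 adjusted over the list alone, mean 0.40, adjusted p = 0.241 with an estimated correlation). Neutrophil chemoattractants (mean 0.75, adjusted p = 0.134 with an estimated correlation), neutrophil markers (0.51, 0.198), NF-kB (0.18, 0.322) and immediate early genes (0.41, 0.354) were called higher with the preset correlation and not with an estimated one. Langerhans and dendritic cell (mean -0.21, adjusted p = 0.134 with an estimated correlation), mast cell (-0.39, 0.134) and endothelial genes (-0.21, 0.518) were called lower in the same way.

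Of the 387 genes called, 164 were higher and 223 lower in the difference. Among the 164, the genotype difference was larger with vehicle than with IMQ in 143 (87.2%), with medians of -0.67 with vehicle and 0.34 with IMQ. For the 223 it was larger with vehicle in 113 (50.7%), with medians of 0.50 and -0.55. The vehicle arrays enter both the difference and the vehicle comparison, so the 2 are not independent. With muscle and adipocyte means as covariates limma called 0 genes, with 2374 at an unadjusted p under 0.05. With the number within each genotype as a block it called 220. Leaving out 1 array gave 149 (without wild-type vehicle 1) to 824 genes (without knockout vehicle 3), and 314 were called without knockout vehicle arrays 3 and 4. Of the 387 genes, 220 were among these 314, and 191 were among the genes called with the number block.

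**Figure D4:**
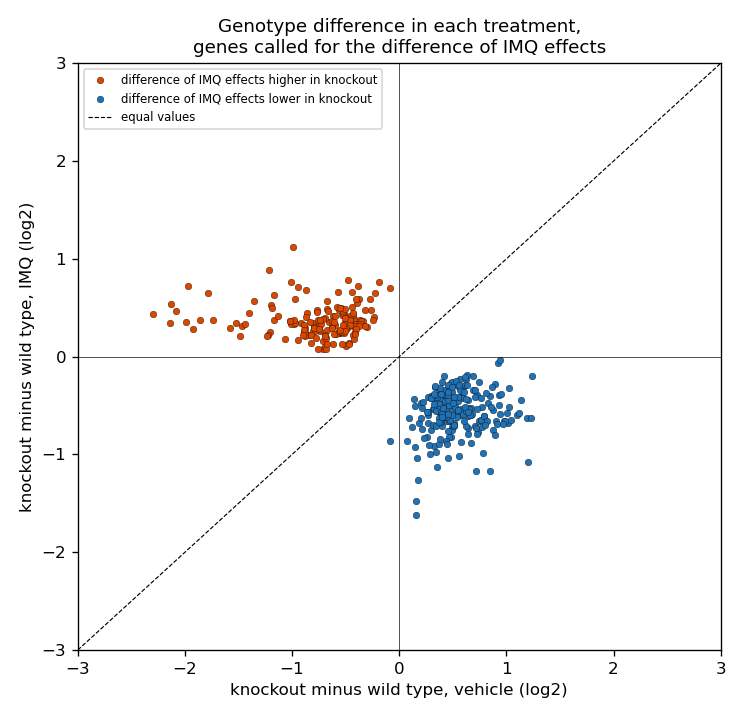
Knockout minus wild type log2 difference with IMQ (vertical axis) against that with vehicle (horizontal axis) for the 387 genes called for the difference of IMQ effects, with equal values on the dashed line. The 164 genes in orange have medians of -0.67 with vehicle and 0.34 with IMQ, and the 223 in blue of 0.50 and -0.55.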

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

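The tests of the muscle and fat share, of the gap within numbered pairs, of dilution as the whole cause, of the splits that part the numbered pairs, of the clock genes and of the genes that differed in both treatments were chosen after the results were seen.

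The 387 genes called for the difference of IMQ effects, with lower stress keratin and antimicrobial genes in knockout vehicle ears, are the first pattern. For the number of genes called for the difference, chance is made unlikely but not excluded. Of 100 drawn splits of genotype within treatment 1, the real one, gave as many genes, and the highest of the others gave 11. It was 1 of 100 too when every split parted the 4 numbered vehicle pairs, where the highest other gave 176. The smallest share that 100 splits can give is 1 of 100. These splits did not count the genes lower in knockout vehicle ears, and the vehicle splits given below are too few to decide on chance there. A share of muscle and fat in the ears stays open as the cause: with muscle and adipocyte means as covariates the stress keratin list differed by 0.76 with a standard error of 0.48 (from 1.41 with 0.36) and the antimicrobial list by 0.56 with 0.25 (from 0.94 with 0.18), and the 80.0% left over the 164 genes higher in the difference (median 0.999 with 0.20 before, 0.80 with 0.28 after) decides nothing, since these were picked for their difference and all calls ended as the effect shrank while its error grew. Dilution of the epidermis by deeper tissue as the whole cause of the lower stress genes in vehicle ears has values against it. The limits were set after these values were seen. The mean of 22 constitutive epidermal genes differed by -0.21 where the stress keratin mean differed by -1.08. The gap of -0.87 was 2.78 times its standard error, with an exact permutation p of 0.0571 (n = 4 and 4). It was lower in the knockout in each of the 4 numbered pairs (-0.99, -0.76, -0.30 and -1.44), whose exact p cannot be under 0.125. Any pairing without knockout array 3 (-2.94) beside wild-type array 4 (-2.97) gives the same signs, so the pairs add little. Knockout array 3 had the lowest muscle mean (7.58) and the highest stress keratin mean (6.21) of its group, which goes with dilution. The largest gap was in pair 4, while knockout array 2 had the highest muscle mean (8.59). Dilution as a part of the cause stays open beside an effect of genotype on vehicle-treated skin; the criterion written beforehand took an exact p of 0.05 or more as speaking for dilution, and was dropped after the result was seen because a missed threshold does not show that both lists fell alike.

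The second pattern is that of clock genes: in vehicle ears 5 of 10 output and period genes and 1 of 5 opposed genes, in lists drawn up after values were seen, were called between genotypes, and the other 9 of the 15 were not. Dbp (1.24 ± 0.20), Per1 (0.73 ± 0.15), Per2 (0.67 ± 0.13), Nr1d2 (0.66 ± 0.14) and Bhlhe41 (0.74 ± 0.15) were higher and Arntl (-0.74 ± 0.14) was lower in the knockout. With IMQ Per1 was lower (-0.79 ± 0.15), the 1 output and period gene called there. The mean of the 10 output and period genes differed by 0.65 with vehicle and -0.37 with IMQ (exact permutation p = 0.0286 for each, n = 4 and 4). That of the 5 opposed genes differed by -0.37 and -0.14 (exact permutation p = 0.0571 and 0.314). For the difference of effects 7 of the 10 and 0 of the 5 were called. A muscle and fat share as the cause stays open. Under the covariates the clock index (output and period genes minus opposed genes) still differed by 0.80 with vehicle (standard error 0.16). This decides little, since the lists were drawn up after values were seen. A difference in clock phase between the groups of mice may contribute but stays open, since the opposed genes other than Arntl, whose median was known when this test was written, differed by -0.28 (exact permutation p = 0.143, n = 4 and 4), and an earlier form of the test, which passed, was dropped because it held Hlf, Nr1d2 and Bhlhe41, whose values had been seen. The hour of collection is not given, so a collection hour that differed between groups and an effect of genotype cannot be told apart.

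The third pattern is that of the 7 genes that differed between genotypes in the same direction in both treatments. DNA linked to the miR-146a gene and carried along with the deleted allele has values against it as the common cause: 0 of the 7 lie among the 200 tested genes nearest to Mir146 in the order of GRCm38.p6, and Cd59a, Entpd4 and Ccl20 lie on other chromosomes (2, 14 and 1). For Lyrm7, 167 tested genes from Mir146 on chromosome 11 and thus beyond a window of 100 on each side, linked DNA stays open, since the length of the carried segment is not known. Direct loss of miR-146a repression has one too, because 1 of the 7, Lyrm7, was higher in the knockout and 6 were lower. Strain differences elsewhere in the genome were not tested, and the 3 genes with predicted names have no place in the reference table, so the count rests on the other 4.

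Other splits of the arrays were counted for the remaining comparisons. For IMQ in wild-type ears 1 of 35 splits, the real one, gave as many genes as the 1126 and the highest other gave 0. In knockout ears it was 1 of 35, with 4634 against 3. Between genotypes with IMQ it was 1 of 35 (37 against 1). In these 3 comparisons no other split gave as many genes as the real one, which makes chance unlikely. It is not excluded, since 1 of 35 is the smallest share possible and was not adjusted over the comparisons. Between genotypes with vehicle, where the numbers were taken to pair the arrays, 8 splits part all 4 pairs, too few for a share under 0.05. The real one gave 141 genes and the highest other 0. The splits that part fewer pairs gave up to 7.

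The difference of IMQ effects passed limma's test for 52 of the 128 named genes. It was higher in the knockout for 24 of them and lower for 28. Higher were Il1a (1.44), Sprr2e (2.55), Defb4 (2.70), Defb3 (2.67), Sprr1a (2.48), Gjb2 (1.70), Lce3d (2.74), Lce3a (1.55), Cdc20 (0.81) and Plk1 (1.16). Also higher were Il33 (1.14), Il1f9 (1.09), Slpi (1.87), Rptn (2.34), Sprr1b (2.24), Gsta4 (2.12), Il1f6 (1.26), Aurkb (1.06), Pla2g4d (1.27) and Defb14 (1.11). The remaining higher ones were Rnf224 (0.79), Crabp2 (1.24), S100a7a (2.11) and Lce3c (1.78). Lower were Alox12e (-1.44), Flg2 (-1.64), Fabp4 (-1.30), Krt15 (-1.49), Dbp (-1.44), Lce1m (-1.48), Tcap (-2.28), Casq1 (-1.54), Pvalb (-1.70) and Myh4 (-2.02). Also lower were Chad (-1.11), Smtnl1 (-1.70), Npr3 (-1.34), Mylpf (-1.58), Tmod4 (-1.33), Nexn (-0.98), Myh3 (-1.43), Atp1b2 (-0.98), Myoc (-1.78) and Omd (-1.21). Further lower ones were Angptl7 (-1.49), Wnk4 (-1.57), Lyz1 (-1.89), Zbtb16 (-1.85), Myoz1 (-1.81), Myom1 (-1.76), Cacna1s (-1.70) and Acan (-1.14). By camera with the preset correlation 15 lists differed in mean effect, with an estimated correlation 3 did and by fry 7, the 3 being the IL-1 and IL-36 family, antimicrobial and cartilage lists. Higher in the knockout were the IL-1 and IL-36 family list (0.58), the antimicrobial proteins list (0.94), the stress keratins and small proline-rich proteins list (1.41), the late cornified envelope and terminal differentiation list (0.40), the neutrophil chemoattractants list (0.75), the neutrophil markers list (0.51), the cell cycle list (0.69), the NF-kB pathway and feedback genes list (0.18) and the immediate early genes list (0.41). Lower in the knockout were the Langerhans and dendritic cell markers list (-0.21), the mast cell markers list (-0.39), the adipocyte markers list (-0.86), the skeletal muscle markers list (-1.42), the cartilage markers list (-0.47) and the blood vessel and lymphatic endothelium list (-0.21).

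One array stood far from the others of its group for 28 of 616 groups of 4 arrays tested, where chance gives about 30.8. Each value is the gap to the nearest array as a share of the range. In the wild-type vehicle group these were the mast cell markers list (array 3, 0.897), Stfa2l1 (array 3, 0.867), Ccl7 (array 4, 0.869), Il1r1 (array 1, 0.917) and Wnk4 (array 1, 0.850). In the wild-type IMQ group these were the NF-kB pathway and feedback genes list (array 3, 0.872), the hair follicle keratins and associated genes list (array 2, 0.830), the skeletal muscle markers list (array 1, 0.839), Ifi205 (array 1, 0.879), Sprr1a (array 4, 0.854), Crabp2 (array 3, 1), Angptl7 (array 4, 0.860), Myoz1 (array 1, 0.927) and Myom1 (array 1, 0.928). In the knockout vehicle group these were the late cornified envelope and terminal differentiation list (array 1, 0.906), the B cell markers list (array 1, 0.927), the sebaceous gland and lipid synthesis list (array 4, 0.904), Irak1 (array 4, 0.875), Cxcl13 (array 1, 0.854), Stfa2l1 (array 3, 0.857), Myoz1 (array 3, 0.882) and Cacna1s (array 3, 0.875). In the knockout IMQ group these were Cxcl13 (array 3, 0.834), Flg2 (array 3, 0.855), Itgam (array 3, 0.871), Il1b (array 3, 0.858), Tpsb2 (array 1, 0.877) and Ccl3 (array 3, 0.837). Knockout IMQ array 3 accounts for 5 of these.

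Clusters without a gene symbol, which enter no comparison above, also responded. Of 8874, 95 were called for IMQ in knockout ears and 6 in wild-type ears, and 0 between genotypes or for the difference of effects.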

How the results depend on the processing

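The block within the vehicle arrays and the fit without knockout vehicle arrays 3 and 4 were chosen after the results were seen. In what follows counts are of genes called in the order wild-type IMQ effect, knockout IMQ effect, genotype with vehicle, genotype with IMQ, difference of effects (1126, 4634, 141, 37 and 387 as fitted). Without dim genes the third became 357 and the fifth 723, fewer genes being tested. With trend and robust options the last 3 became 343, 85 and 652, and with array weights the third became 237. With only the groups compared the third became 15 and the fourth 11, holding 14 of the 141 and 11 of the 37. For the difference all groups are compared already. Requiring a 2-fold change gave 269, 821, 45, 13 and 210. With muscle and adipocyte means as covariates the counts were 535, 612, 2, 10 and 0. That fit turned Myoz1 in the knockout IMQ effect (0.11), Cacna1s in the difference (0.0029), the endothelial list with vehicle (-0.0505) and in the difference (0.13) and the immediate early list in the difference (-0.15). The 2 covariate lists have no value in it. With the number within each genotype as a block, which pairs vehicle with IMQ arrays, the difference became 220. With the number as a block over all arrays genotype with vehicle became 240, and with the block in the vehicle arrays alone 75. Equal numbers outside the vehicle arrays did not pair, so neither the 220 nor the 240 is a check of the vehicle pairing. The cause of these changes was not tested unless stated.

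Leaving out 1 array gave 769 to 1210, 3623 to 4567, 37 to 474, 7 to 80 and 149 to 824 genes, and 564 to 822 genes called the same way in both genotypes (800 as fitted). For genotype with vehicle the count moved over 1.5 times without wild-type vehicle 1 (37), 2 (83) or 3 (38) and knockout vehicle 2 (79), 3 (474) or 4 (47). For genotype with IMQ it did so without wild-type IMQ 1 (24), 2 (7) or 4 (16) and knockout IMQ 2 (17), 3 (80) or 4 (13). For the difference it did so without wild-type vehicle 1 (149), 2 (257) or 3 (172), wild-type IMQ 2 (173) or 4 (162), knockout vehicle 2 (238), 3 (824) or 4 (166) and knockout IMQ 1 (199) or 4 (220). Of the named genes called in each comparison, 55 of 69, 107 of 111, 14 of 36, 5 of 16 and 34 of 52 kept their call without any 1 array, and none changed sign. Genes ranked because the arrays of the 2 groups did not overlap cannot change sign in this way, so their sign is no check. The 3 planned seed-site alternatives were not run. Genes near the array floor, Mir146 among them, cannot show a fall.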
